A study of Equus caballus with 17 samples.

How the data were processed

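Small RNA was sequenced in 17 horse (Equus caballus) libraries, 13 from testis and 4 from sperm. Per the labels, small RNA was isolated with TRIzol, sperm RNA received a shorter DNase treatment followed by phenol:chloroform purification, and testis RNA received a longer DNase treatment. Per the labels, libraries were made by adapter ligation, reverse transcription, PCR and size selection. The submitters' processing notes name Trimmomatic (version not given) for trimming and EquCab3.0 as the genome build. The aligner, the counting program and the annotation release were not given in the sources used here.

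The deposited table held 1763 entries with a count column and a normalised column for each library. The deposited count values were whole read counts, as the values themselves showed. The deposited normalised columns were in RPM, and each equalled the count divided by the library's column total and scaled to RPM, within 0.005 RPM. Per-sample columns were matched to samples by title number. The number 4 is held by an Adult and a Sperm sample, and its columns were told apart by their prefix, on the inference that se marks sperm, since the columns numbered 1 and 2 carry it and only sperm titles have those numbers. A further column of totals exceeded the sum of the 17 libraries, by counts whose origin the sources used here do not give, and was not analysed here.

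Of the entries, 302 named an annotated mature miRNA with its precursor, and 1461 were predicted hairpins with a sequence and a position. The annotated entries covered 274 mature miRNAs, of which 22 had more than 1 entry. For the 12 of these with at least 1000 counts, the smaller entry held at least 0.898 of the larger (median 0.995), so the same reads were counted for each precursor. The entry with the highest total was therefore kept for each mature miRNA. The separate names miR-17 and miR-106a held nearly the same counts (4829 and 4830 in Infant, 40468 and 38765 in Pre-puber). Whether the same reads were counted for both was not tested, and both enter the lists and counts below as separate miRNAs. The table gave no position for annotated miRNAs. Its names carry the prefix eca-, which is left out of the text.

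Comparisons used the counts of annotated miRNAs only, a choice made from the structure of the table before any test was run, because many predicted hairpins shared sequence with each other. Levels are in CPM of the annotated counts after TMM scaling. TMM levels are relative, so scaled levels of a library need not sum to its total. Predicted hairpins were tested separately with the library sizes and scaling factors of the annotated miRNAs. A fit of all entries together was added as an alternative.

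Groups were the stages in the labels: Infant (n = 3), Pre-puber (n = 3), Puber (n = 3), Adult (n = 4) and Sperm (n = 4). Infant 31a and 31b, and Pre-puber 3a and 3b, share a title number. The labels do not say whether they came from 1 animal, so they were kept as separate libraries, with summed libraries as an alternative. Differential abundance was tested with edgeR 4.0.16 in R 4.3.3 by quasi-likelihood F tests, after filterByExpr by group and TMM scaling, with Benjamini-Hochberg adjusted p under 0.05. The 13 testis libraries were fitted together (184 miRNAs tested), and Sperm and Adult in a fit of their 8 libraries (162 tested). The fits were scaled separately, so Adult levels differ between them. Standard errors of log2 fold changes were derived from the F statistic and are approximate.

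Lists of miRNAs were tested with camera (limma 3.58.1) at a preset correlation of 0.01, for lists with at least 3 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The 22 lists were the let-7 family, the miR-17-92 cluster and its paralogs, the miR-34/449 family, the X-linked miR-506 family region, the pluripotency miR-302/371 clusters, the imprinted DLK1-DIO3 region, the miR-200 family (epithelium), stromal and smooth muscle, striated muscle, blood cells, endothelium (miR-126), gonadal soma (miR-202), miRNAs reported in undifferentiated spermatogonia, the miR-183/96/182 cluster, neural and liver (off-tissue), the miR-15/16, miR-29, miR-30 and miR-181 families, HOX-cluster miR-10/196/615, miR-99/100/125 and the miR-23/24/27 clusters. Numbers of detected miRNAs (at least 5 counts) and the share of counts in the 10 most abundant miRNAs were compared by exact two-sided permutation tests. Groups, comparisons, lists, tests and the naming rule were fixed before the data were examined.

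For each comparison of 2 groups, the text names the 12 largest rises and the 12 largest falls among miRNAs with adjusted p under 0.05, a mean of at least 50 CPM in either group and no overlap between the libraries of the groups. It also names the 10 most abundant miRNAs of each group, 2 to 4 of the most abundant members of each list, and the 10 miRNAs with the smallest p over the testis stages. Where all libraries of a group had no count, a fold is given as a bound against 3 counts over the group. Where a group held 1 to 3 counts, the ratio of pooled levels has an exact 95% counting interval. The reads carry no molecular identifiers, so such intervals and bounds cover counting error only. The EquCab3.0 sequence was not used, so no check rests on the genome itself. X-linked miRNAs were those whose precursors lie on the X chromosome in the supplied gene table, which is of another horse assembly.

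The alternatives fixed before the data were examined were DESeq2 1.42.0 and limma-voom as tests, scaling by median-of-ratios size factors, by upper quartiles or by the total count alone, no filter and a stricter filter of 10 CPM, a minimum of 2-fold, other treatments of precursor entries, other sets of libraries in the fit, summed title numbers, fry and an estimated correlation for the lists, other detection limits and numbers of abundant miRNAs, thinning to 1481718 annotated counts for detection, and each library left out in turn. Alternatives chosen after seeing the data were the fit of all entries, the list tests without Pre-puber 14 or Sperm 2, and Sperm against Adult without its 3 most abundant miRNAs or with thinned libraries. The tests were tried on simulated data with the depths of these libraries, with 20 miRNAs changed by each of 2-fold, 4-fold and 8-fold. At 4-fold, the percentage recovered was 60 for Pre-puber against Infant, 90 for Puber against Pre-puber, 65 for Adult against Puber, 75 for Adult against Infant and 90 for Sperm against Adult, and false calls numbered 0 to 2 per comparison. No simulated library lay apart from its group, as Pre-puber 14 does, so these percentages do not show what the comparisons with Pre-puber could find. Hairpins were grouped by shared stretches of 14 bases with igraph 2.1.4. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.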

Results

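Small RNA was measured in horse testis at 4 stages and in sperm, to follow small RNAs over spermatogenesis. Total counts over all entries ranged from 1.94 to 17.9 M (mega) per library, and counts of annotated mature miRNAs from 1.48 to 13.1 M. Annotated counts averaged 10.5 ± 1.61 M in Infant (SD, n = 3), 9.85 ± 2.83 M in Pre-puber (n = 3), 4.84 ± 1.08 M in Puber (n = 3), 3.60 ± 1.07 M in Adult (n = 4) and 1.80 ± 0.36 M in Sperm (n = 4), so depth differed with the group. The labels do not say that the replicates are separate animals, so p-values measure only the spread between these samples.

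Ranks in this paragraph are among annotated miRNAs and leave out predicted hairpins. By level, the hairpins holding let-7i (106300 CPM in Infant) and miR-202 (64260 in Adult) would stand within the 10 most abundant of those groups. In Infant testis, miR-99a and miR-26a led the libraries, at 380500 ± 102500 and 260800 ± 166300 CPM (SD, n = 3). They were followed by miR-10b, let-7f, let-7c, let-7a, let-7g, miR-21, miR-100 and miR-125b-5p. The same 10 were the most abundant annotated miRNAs in Pre-puber. In Puber, miR-509a-5p, a member of an X-linked miRNA family expressed in testis, took the place of miR-125b-5p at 28900 ± 3329 CPM (n = 3). In Adult, miR-21 led at 103000 ± 31780 CPM (n = 4). miR-34c, which is abundant in meiotic and later germ cells, was in position 10 at 36940 ± 4088 CPM. In Sperm, miR-191a led at 705800 ± 356800 CPM (n = 4). It was followed by miR-30d at 181500 ± 59190, miR-34c at 130200 ± 86420, miR-21, miR-26a, miR-99a, miR-340-5p, miR-449a, let-7a and miR-10b. The most abundant miRNA held 37.8%, 48.6% and 51.7% of annotated counts in Sperm 1, 3 and 4, where it was miR-191a. It held 16.6% in Sperm 2, where it was miR-34c.

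Annotated miRNAs with at least 5 counts numbered 168 ± 3.21 in Infant (SD, n = 3), 178 ± 5.86 in Pre-puber (n = 3), 185 ± 1.73 in Puber (n = 3), 181 ± 7.41 in Adult (n = 4) and 142 ± 7.75 in Sperm (n = 4). From Adult testis to Sperm the number dropped by 38.8, with an exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries allow, and an adjusted p = 0.143 over 5 comparisons. The other exact p-values for detection were 0.10 (Pre-puber against Infant, the smallest that 3 against 3 allow), 0.30 (Puber against Pre-puber), 0.429 (Adult against Puber) and 0.0857 (Adult against Infant), with adjusted values from 0.167 to 0.429. Depth entered these numbers: with all libraries thinned to the smallest total, the difference of Adult against Puber went from -4.25 to 0.667, the other sign, and that of Adult against Infant from 12.4 to 24.7 (exact permutation p = 0.0286, the smallest that 3 against 4 libraries allow). Thinned in this way, Adult 13, 20, 33 and 4 held 170, 164, 172 and 170 and Sperm 1, 2, 3 and 4 held 137, 145, 143 and 129, so the drop in Sperm was smaller but remained. The 10 most abundant miRNAs held 81.3 ± 3.21% of annotated counts in Infant, 77.3 ± 2.69% in Pre-puber, 74.2 ± 4.75% in Puber, 71.9 ± 4.07% in Adult and 80.5 ± 3.80% in Sperm. None of the 5 comparisons of this share passed the threshold by the exact permutation test (p = 0.30, 0.40, 0.486, 0.0571 and 0.0857 in the same order, adjusted p 0.214 to 0.486).

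Across the 4 testis stages, the X-linked miR-509a-5p gave the smallest p, with 277 ± 92.0 CPM in Infant (SD, n = 3), 14330 ± 12930 in Pre-puber (n = 3), 28900 ± 3329 in Puber (n = 3) and 18830 ± 5055 in Adult (n = 4). The germ cell miRNA miR-34b-5p had its highest mean in Adult, with means from 1.00 ± 0.71 CPM in Infant to 19.5 ± 30.3, 459 ± 186 and 1195 ± 169. miR-499-5p, encoded in an intron of a muscle myosin gene, stood at 35.2 ± 3.90, 29.6 ± 9.88, 99.1 ± 31.9 and 146 ± 21.9 CPM. In the other direction, miR-99a stood at 380500 ± 102500 CPM in Infant and 54810 ± 16460 in Adult, miR-135a at 890 ± 361 and 47.4 ± 18.4, and miR-299, from the imprinted DLK1-DIO3 region, at 320 ± 42.5 and 44.6 ± 5.73. The rest of the 10 miRNAs with the smallest p were miR-411, miR-873, let-7d and miR-335, each with its highest mean in Infant. In all, 88 of 184 tested miRNAs (47.8%) changed over the stages by the edgeR test (169 with all entries in the fit), and 99 had an unadjusted p under 0.05. Of the 88, 32 had their highest mean in Infant, 10 in Pre-puber, 14 in Puber and 32 in Adult.

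**Figure D1:**
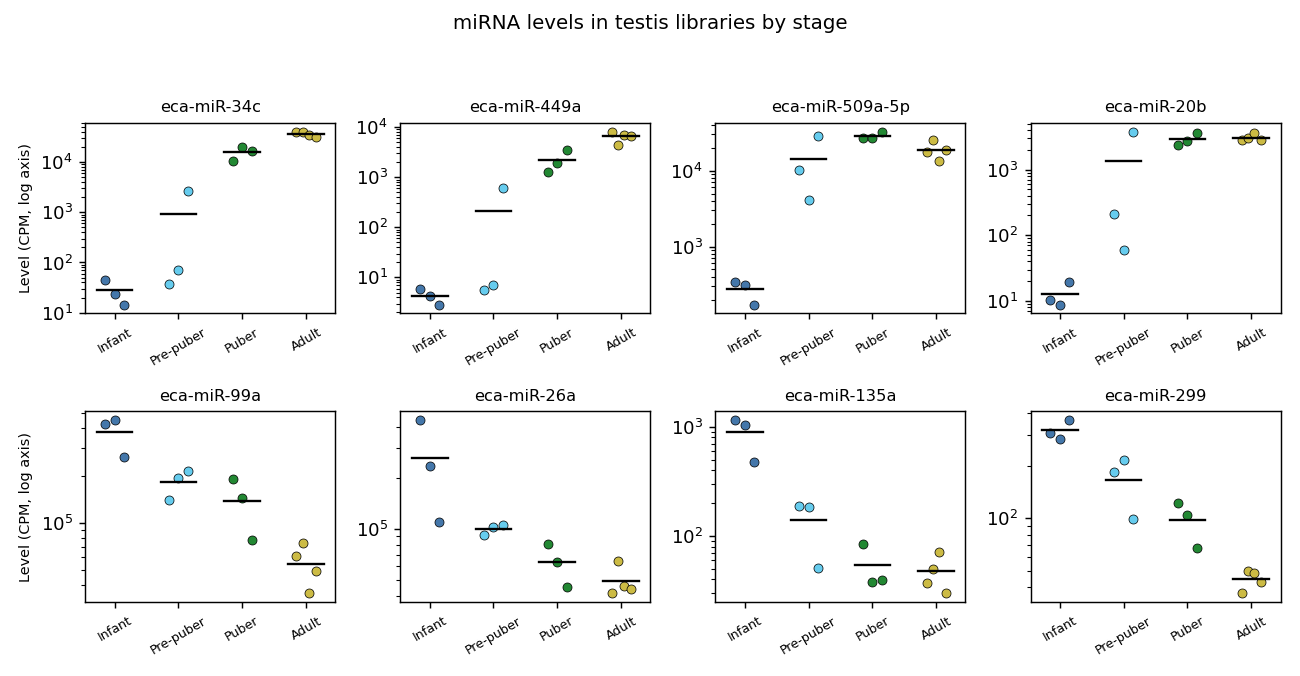
Levels of 8 miRNAs in the 13 testis libraries, in CPM on log axes, by stage; points are libraries and bars are group means. miR-34c, miR-449a, miR-509a-5p and miR-20b lie lowest in Infant, miR-99a, miR-26a, miR-135a and miR-299 lie highest there, and Pre-puber 14 lies above Pre-puber 3a and 3b for the first 4.

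The first 2 principal components of log2 CPM over 190 miRNAs held 69.9% and 10.0% of the variance of the testis libraries. Pre-puber 14 lay apart from the other Pre-puber libraries, at 5.22 on the first component against -12.4 and -13.1 for Pre-puber 3a and 3b and 5.65, 9.65 and 12.6 for Puber 10, 11 and 19. For miR-34c it held 2621 CPM, against 37.7 in 3a and 70.5 in 3b.

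**Figure D2:**
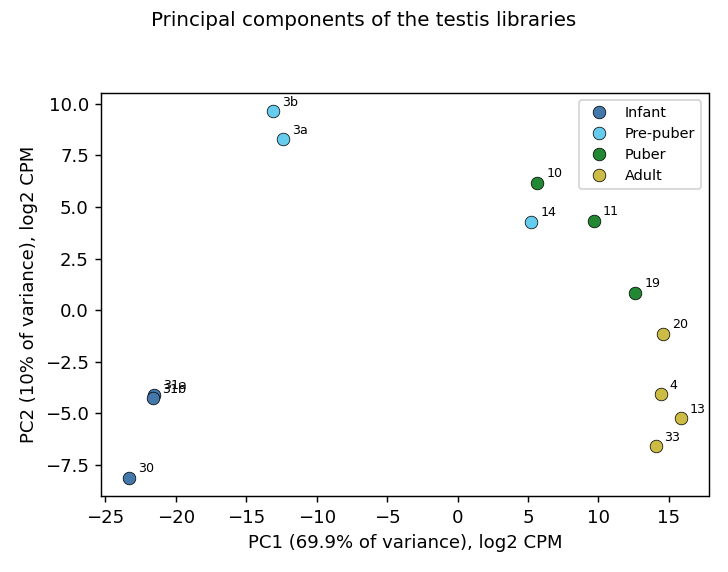
Principal components of the 13 testis libraries from log2 CPM, each point 1 library with its title number and the color of its stage. The first component (69.9% of variance) runs from Infant at -23.3 to Adult at 15.9, and Pre-puber 14 lies beside Puber 10.

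The comparison of Pre-puber with Infant testis asks what changes before puberty. X-linked miR-509a-5p rose 51.7-fold (log2 fold change 5.69 ± 0.66 SE, adjusted p = 0.000186), from 277 ± 92.0 CPM (SD, n = 3) to 10080, 4054 and 28840 CPM in Pre-puber 3a, 3b and 14. miR-20b, a paralog of the growth-linked miR-17-92 cluster, rose from 12.9 ± 5.88 CPM to 212, 59.4 and 3788 CPM in the same libraries (log2 fold change 6.71 ± 1.26, adjusted p = 0.0026). miR-26a and miR-99a fell, by a log2 fold change of -1.39 ± 0.41 (adjusted p = 0.0242) from 260800 ± 166300 to 99770 ± 6850 CPM, and of -1.06 ± 0.36 (adjusted p = 0.0492) from 380500 ± 102500 to 182300 ± 38390 CPM. miR-135a fell to 142 ± 78.7 from 890 ± 361 CPM, and let-7d to 1013 ± 313 from 3285 ± 523 CPM.

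By the naming rule, miR-8908j, miR-514a, miR-8908g, miR-17, miR-106a, miR-182, miR-183, miR-20a, miR-93 and miR-9a also rose, with log2 fold changes from 1.21 to 5.45. Several of these folds rested on Pre-puber 14: without it the log2 fold change was 3.64 in place of 5.45 for miR-8908j, 3.48 in place of 5.28 for miR-8908g, 4.05 in place of 5.34 for miR-514a, 1.56 in place of 2.87 for miR-17 and 1.48 in place of 2.80 for miR-106a. It was 3.43 for miR-20b, 4.68 for miR-509a-5p, 3.81 in place of 4.97 for miR-508-5p and 3.92 in place of 5.16 for miR-509b. miR-873, miR-211, miR-708, miR-361-5p, miR-369-5p and miR-411 also fell, with log2 fold changes from -3.69 to -0.90. All 5 tested members of the X-linked miR-506 family region rose (5 when adjusted over the list alone), among them miR-508-5p and miR-509b, and the list passed the camera test (adjusted p = 4.4e-06, and adjusted p = 0.339 with an estimated correlation). All 3 members of the miR-183, miR-96 and miR-182 cluster, which are transcribed together, rose (3 when adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.757 with an estimated correlation), with miR-182 at 236 ± 160 against 41.8 ± 28.7 CPM. Of 15 tested members of the imprinted DLK1-DIO3 region, 3 fell and 12 were not called (3 lower when adjusted over the list alone, camera adjusted p = 0.00163, adjusted p = 0.797 with an estimated correlation, and 0.102 without Pre-puber 14). Within that list miR-411 fell from 17750 ± 3252 to 9493 ± 2496 CPM. miR-379 stood at 30360 ± 1769 and 23140 ± 13880 CPM and was not called. Of 8 members of the miR-17-92 cluster and its paralogs, 5 rose (camera adjusted p = 0.0658), with miR-17 and miR-106a, of nearly the same counts, both among them. In the miR-34 and miR-449 family, miR-34c, miR-449a and miR-34b-5p were called higher out of 5 members (camera adjusted p = 0.465). None of these calls remained without Pre-puber 14, where the log2 fold change of miR-34c was 0.95 (adjusted p = 0.18). miR-371-5p, the tested member of the pluripotency clusters, rose to 11.8 ± 1.95 from 0.299 ± 0.37 CPM. No member of the blood cell list (5), the stromal list (3) or the spermatogonia list (3), nor miR-126-5p of endothelium, was called. In the lists described, the counts were the same when adjusted over the list alone.

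edgeR called 44 of 184 miRNAs, 29 higher and 15 lower, and 62 had an unadjusted p under 0.05. The libraries of the 2 groups did not overlap for 66 miRNAs (35.9%). Chance gives 10% if all libraries are separate samples, and more if those sharing a title number came from 1 animal. The median log2 change of all tested miRNAs was 0.16. Scaling moved the split: it was 36 higher and 5 lower without scaling beyond the total (median 0.58), 25 and 17 by upper quartiles (median -0.11) and 39 and 7 with all entries in the fit (median 0.53). Summing the libraries that share a title number gave 29 calls, 25 higher and 4 lower, so most falls were lost. The calls of miR-211, miR-26a, miR-361-5p, miR-369-5p, miR-411, miR-708, miR-99a and miR-9a then ended. Fitting these groups alone gave 26, and leaving out Pre-puber 14 gave 33, of which 31 were among the 44. There was then no call for miR-99a, miR-26a, miR-411, miR-369-5p and miR-9a. Leaving out 1 library at a time ended 12 of the 29 named calls at least once. Beyond Pre-puber 14, Pre-puber 3b carried those of miR-182 (log2 fold change 1.79 without it, also lost without Infant 31b or 30) and miR-96 (1.77). Those of miR-26a (-1.42 to -0.77, the weakest without Infant 31a), miR-99a (-1.18 to -0.90), miR-211 (-1.58 to -1.40) and miR-708 (-1.61 to -1.33) ended without each of at least 4 libraries. The calls of miR-369-5p (without Infant 30 or Pre-puber 3b), miR-411 and miR-9a (Infant 30), miR-34b-5p (Infant 31a or 30) and miR-449a (Infant 31b) also ended without libraries other than Pre-puber 14. Other folds moved by over 1.5 times with the call kept. Without Pre-puber 3b the log2 fold change was 1.76 for miR-183 and 7.29 for miR-20b. Without Infant 31a it was 3.15 for miR-182, 6.18 for miR-509b, 5.71 for miR-508-5p and 6.03 for miR-8908g. Without Infant 31b it was 6.97 for miR-371-5p (4.57 without Infant 30, in place of 5.17) and 4.92 for miR-34b-5p (in place of 4.25).

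The comparison of Puber with Pre-puber testis asks what changes at puberty. miR-499-5p rose 3.35-fold, from 29.6 ± 9.88 to 99.1 ± 31.9 CPM (SD, n = 3 each, log2 fold change 1.74 ± 0.35 SE, adjusted p = 0.0285). The only other call, miR-9052, lies outside the naming rule and is named after its values were seen. It had 47 counts in Puber and 1 in Pre-puber, a ratio of 91.6 with a 95% counting interval of 15.7 to 3694. The miR-34 and miR-449 family lay higher as a list (camera adjusted p = 0.000751, and adjusted p = 0.295 with an estimated correlation). None of its 5 members was called over all miRNAs and 4 were when adjusted over the list alone. miR-34c stood at 909.6 ± 1482 CPM in Pre-puber and 15910 ± 5034 in Puber, miR-449a at 210.5 ± 354 and 2238 ± 1167, and miR-34b-5p at 19.5 ± 30.3 and 459 ± 186. None of the other 12 tested lists was called with all libraries, but without Pre-puber 14 camera called 3 lists in place of 1. The nearest were blood cells (median log2 fold change -0.97, camera adjusted p = 0.0795, 2 of 5 lower when adjusted over the list alone) and the HOX-cluster miRNAs (median -1.96, camera adjusted p = 0.0802, 2 of 4 lower when adjusted over the list alone). miR-150 stood at 472 ± 37.4 CPM in Pre-puber and 181 ± 45.8 in Puber, and miR-10b at 105700 ± 37450 and 74250 ± 19500.

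edgeR called 2 of 184 miRNAs, both higher in Puber, with 34 at an unadjusted p under 0.05, while DESeq2 called 16 and limma-voom 19. The libraries of the groups did not overlap for 49 miRNAs (26.6%), where chance gives 10% for separate samples, and more if Pre-puber 3a and 3b came from 1 animal. This count rested on Pre-puber 14: without it, edgeR called 30 miRNAs, 24 higher and 6 lower, and leaving out any of the other libraries gave 0 or 1. With all entries in the fit it was 105 calls, 3 higher and 102 lower, at a median log2 change of -1.93 against -0.02. The call of miR-499-5p ended under 10 of 19 alternatives and took the other sign (-0.13) with all entries in the fit.

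Between Adult and Puber testis no miRNA was called by edgeR. The 3 miRNAs with the smallest p, named after their values were seen, were miR-450b-5p at 4738 ± 777 CPM in Adult (SD, n = 4) and 11700 ± 3304 in Puber (n = 3), miR-542-5p at 13.4 ± 1.10 and 75.9 ± 36.7. The last was miR-199b-5p, a stromal miRNA, at 1841 ± 762 and 6605 ± 2387, each with adjusted p = 0.0547. camera called 0 of 13 lists (3 at an unadjusted p under 0.05), and fry called 1, the stromal list. The miR-183, miR-96 and miR-182 cluster came nearest (camera adjusted p = 0.062, median log2 fold change -1.52, 0 of 3 called and 3 lower when adjusted over the list alone), followed by the miR-34 and miR-449 family (camera adjusted p = 0.0875, median 1.38). Members of the stromal list (median -0.72, camera adjusted p = 0.167) gave 2 lower of 3 when adjusted over the list alone, and members of the DLK1-DIO3 region 4 lower of 15. Of 184 tested miRNAs, 34 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 10. A fit of these 7 libraries alone called 19, 5 higher and 14 lower. For 44 miRNAs (23.9%) the groups did not overlap, where chance gives 5.71%. The count was 7 without Puber 19 and 7 without Adult 20.

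The comparison of Adult with Infant testis spans the development of the testis. miRNAs of the miR-34 and miR-449 family, which are abundant in meiotic and later germ cells, rose: miR-34c from 28.08 ± 16.01 CPM (SD, n = 3) to 36940 ± 4088 (n = 4; log2 fold change 10.36 ± 1.59 SE, adjusted p = 0.000201), miR-449a from 4.33 ± 1.54 to 6530 ± 1581, and miR-34b-5p from 1.00 ± 0.71 to 1195 ± 169. X-linked miR-509a-5p rose 67.9-fold to 18830 ± 5055 CPM (log2 fold change 6.09 ± 0.66, adjusted p = 6.2e-05). miR-8909 rose from 0.359 ± 0.36 CPM (7 counts over 3 libraries) to 688 ± 232. The 2 most abundant miRNAs of Infant testis fell, miR-99a from 380500 ± 102500 to 54810 ± 16460 CPM (log2 fold change -2.80 ± 0.34, adjusted p = 9.5e-05) and miR-26a from 260800 ± 166300 to 48970 ± 10640 CPM (-2.41 ± 0.38, adjusted p = 0.000209). miR-135a fell from 890 ± 361 to 47.4 ± 18.4 CPM, and miR-675, which is cut from the imprinted H19 transcript, from 146 ± 93.6 to 12.5 ± 2.44 CPM.

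The other miRNAs with the largest rises were miR-8908j, miR-20b, miR-8908g, miR-8908k, miR-767-5p, miR-105 and miR-514a, with log2 fold changes from 5.38 to 7.93. The other large falls were those of miR-1298, miR-211, miR-873, miR-542-5p, miR-299, miR-335, miR-150 and miR-199b-5p, from -3.94 to -2.13. All 5 tested members of the X-linked miR-506 family region rose (5 when adjusted over the list alone, camera adjusted p = 0.00344, and adjusted p = 0.475 with an estimated correlation). Of the miR-34 and miR-449 family, 4 of 5 rose (4 over the list alone, camera adjusted p = 0.0177, and adjusted p = 0.475 with an estimated correlation) and miR-34a, at 109 ± 50.2 CPM in Infant and 66.02 ± 12.12 in Adult, was not called. Of the miR-17-92 cluster and its paralogs, 7 of 8 rose (7 over the list alone, camera adjusted p = 0.0139, and adjusted p = 0.475 with an estimated correlation), among them miR-20b from 12.9 ± 5.88 to 3058 ± 348 CPM and miR-17 from 222 ± 37.7 to 2666 ± 753 CPM. The 7 also include miR-106a, with nearly the same counts as miR-17, so these may not be separate members. Of the 15 tested members of the imprinted DLK1-DIO3 region, 9 fell, 1 rose and 5 were not called (the same numbers over the list alone, camera adjusted p = 0.0177, and adjusted p = 0.519 with an estimated correlation). In that region miR-379 fell from 30360 ± 1769 to 8137 ± 5981 CPM and miR-411 from 17750 ± 3252 to 4105 ± 98.1. miR-409-5p rose from 828.5 ± 484 to 2114 ± 416 CPM, a call that ended by upper quartile scaling and took the other sign (-0.38) with all entries in the fit.

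Some markers of other cell types moved in the same comparison. Their lists were incomplete, with 3 annotated members for stroma and smooth muscle, 1 for striated muscle, 5 for blood cells and 3 for undifferentiated spermatogonia. The other members of these lists had no annotated entry. Of the stromal and smooth muscle list, miR-199a-5p fell from 29840 ± 7158 to 9365 ± 1525 CPM and miR-199b-5p from 8068 ± 2255 to 1841 ± 762. miR-145 stood at 3779 ± 446 and 5442 ± 1743 and was not called (2 of 3 lower, camera adjusted p = 0.242). Of the blood cell list, miR-155 and miR-150 fell and miR-486-5p, miR-142-5p and miR-451 were not called (camera adjusted p = 0.211). miR-499-5p of the striated muscle list rose to 146 ± 21.9 from 35.2 ± 3.90 CPM. Both tested off-tissue miRNAs rose (miR-9a to 418 ± 141 from 94.3 ± 9.29, miR-122 to 39.4 ± 13.8 from 11.3 ± 3.21 CPM). miR-126-5p of endothelium was not called, at 328 ± 104 CPM in Infant and 446 ± 150 in Adult. Of the let-7 family 4 of 7 fell (camera adjusted p = 0.0878), of the miR-99, miR-100 and miR-125 group 3 of 5 fell (camera adjusted p = 0.16). Both members of the miR-181 family fell, with miR-181a at 1579 ± 446 CPM in Adult and 5638 ± 949 in Infant. Of the miRNAs reported in undifferentiated spermatogonia, miR-146a fell and miR-21 and miR-146b-5p were not called (camera adjusted p = 0.986). miR-424 alone fell of 7 members of the miR-15/16 family (camera adjusted p = 0.986), and miR-371-5p of the pluripotency clusters rose to 4.00 ± 2.49 CPM. No member of the miR-30 family (4, camera adjusted p = 0.986), the HOX-cluster list (4, 0.767) or the miR-183, miR-96 and miR-182 cluster (3, 0.988) was called. The miR-200, miR-29 and miR-23/24/27 lists had 0 members among the annotated miRNAs of the table, as had gonadal soma (miR-202). Counts were the same when adjusted over the list alone, except for the miR-15/16 family with 0.

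edgeR called 95 of 184 miRNAs, 48 higher and 47 lower in Adult, with 104 at an unadjusted p under 0.05. The groups did not overlap for 92 miRNAs, where chance gives 5.71% for separate samples, and more if Infant 31a and 31b came from 1 animal. The median log2 change was -0.14, and the split followed the scaling: 84 higher and 21 lower without scaling beyond the total (median 0.82), 52 and 35 with median-of-ratios factors (median 0.04), 40 and 65 by upper quartiles (median -0.52) and 30 and 119 with all entries in the fit (median -1.90). The calls of let-7f, miR-432, miR-125a-5p and miR-122 ended under 4 or more alternatives each, and miR-122 took the other sign (-0.20) with all entries in the fit. Leaving out 1 library at a time ended 7 of the 46 named calls at least once: those of let-7f, miR-432 and miR-424 under 5 libraries each, miR-122 and miR-409-5p under 3 each, miR-125a-5p without Infant 30 (-0.87) or Adult 20 (-1.30), and miR-146a without Infant 31a (-1.05). It also moved log2 fold changes by over 1.5 times in fold. Without Infant 31a they were -1.80 for miR-26a, -0.82 for miR-424, -2.08 for miR-542-5p, 4.98 for miR-508-5p, 6.12 for miR-509b, 8.24 for miR-8908g and 11.75 for miR-8909. Without Infant 31b they were 9.15 for miR-8908k (in place of 6.96), 5.38 for miR-371-5p (in place of 3.58) and 10.86 for miR-34b-5p. Without Infant 30 they were 6.47 for miR-105, -2.89 for miR-675, 2.97 for miR-371-5p and 10.30 for miR-8909. Without Adult 20 they were -5.30 for miR-1298 (in place of -3.94) and -2.56 for miR-379. Without Adult 4 they were -3.90 for miR-873 and 2.96 for miR-371-5p, and without Adult 33 -2.22 for miR-424.

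The comparison of Sperm with Adult testis sets germ cells at the end of spermatogenesis against the whole organ. miR-191a rose 101.5-fold, from 6955 ± 1404 to 705800 ± 356800 CPM (SD, n = 4 each; log2 fold change 6.67 ± 0.52 SE, adjusted p = 1.8e-17). miR-122, known as the main miRNA of liver, rose 687-fold, from 30.2 ± 13.3 to 20760 ± 4794 CPM (log2 fold change 9.42 ± 0.58, adjusted p = 1.2e-21), and miR-205, an epithelial miRNA, from 1.37 ± 0.15 to 676 ± 369 CPM. In the other direction, X-linked miR-509a-5p fell from 14020 ± 3652 to 8.46 ± 5.27 CPM (log2 fold change -10.65 ± 0.63, adjusted p = 3.1e-22), miR-450b-5p from 3566 ± 890 to 2.92 ± 3.18 (-10.41 ± 0.72), and smooth muscle miR-145 from 3992 ± 999 to 9.96 ± 4.43 (-8.61 ± 0.60). miR-514a had no count in sperm and was at least 344-fold lower than its 248 ± 90.0 CPM in Adult, taking 3 counts over the sperm libraries as the limit.

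The other largest rises were those of miR-124, miR-216b, miR-212, miR-499-5p, miR-8908k, miR-135a, miR-190b, miR-146b-5p and miR-16, with log2 fold changes from 4.08 to 6.73. miR-450c, miR-20b, miR-450a, miR-199a-5p, miR-424 and miR-432 also fell, by log2 fold changes from -8.57 to -7.00. miR-503 and miR-767-5p had 2 counts each in sperm, ratios of 529 (95% counting interval 146 to 4370) and 120 (33.3 to 995) below Adult. All 4 tested members of the X-linked miR-506 family region fell (4 over the list alone, camera adjusted p = 0.0608), with miR-509b and miR-508-5p at least 34.6-fold and 25.5-fold lower. All 3 members of the stromal and smooth muscle list fell, with miR-199a-5p at 55.4 ± 23.6 CPM in Sperm and 7061 ± 1764 in Adult (3 over the list alone, camera adjusted p = 0.0608). miR-126-5p of endothelium fell to 42.45 CPM from 341 CPM. Of 5 blood cell miRNAs 2 rose, miR-155 to 5693 ± 894 from 679 ± 165 CPM and the red blood cell miRNA miR-451 to 1485 ± 486 from 64.4, 63.7, 696 and 92.2 CPM in Adult 13, 20, 33 and 4 (log2 fold change 2.69, 4.33 without Adult 33, and 1.63 with no call without Adult 20), and 3 were not called (camera adjusted p = 0.40). All 3 off-tissue miRNAs rose (camera adjusted p = 0.0659), with neural miR-124 at 77.2 ± 24.1 CPM in Sperm and 0.640 ± 0.78 in Adult. miR-499-5p of the striated muscle list rose to 6377 ± 2273 from 110 ± 26.7 CPM.

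Among the germ cell and growth-linked lists, 4 of 5 members of the miR-34 and miR-449 family rose (camera adjusted p = 0.259). miR-34c stood at 130200 ± 86420 CPM in Sperm and 27470 ± 3357 in Adult and miR-449a at 45620 ± 29190 and 4921 ± 1465, while miR-34a fell to 8.68 ± 2.03 from 49.1 ± 9.86 CPM. All 4 members of the miR-30 family rose (camera adjusted p = 0.0669), with miR-30d at 181500 ± 59190 against 14160 ± 3065 CPM. Of the miR-17-92 cluster and its paralogs 5 rose, 1 fell and 2 were not called (camera adjusted p = 0.40). miR-93 stood at 17130 ± 8735 against 1572 ± 332 CPM and miR-20b at 8.62 ± 6.94 against 2268 ± 202. Of the miR-15/16 family 3 rose and 4 fell (camera adjusted p = 0.395). miR-16 stood at 29300 ± 11590 against 1728 ± 539 CPM and miR-195 at 23.3 ± 12.7 against 1670 ± 721. All 3 members of the miR-183, miR-96 and miR-182 cluster rose (camera adjusted p = 0.163). So did 2 of 3 miRNAs reported in undifferentiated spermatogonia, miR-146a and miR-146b-5p (camera adjusted p = 0.259). Of 13 members of the DLK1-DIO3 region 9 fell, 2 rose and 2 were not called (camera adjusted p = 0.0711), with miR-379 at 189 ± 52.6 against 5919 ± 3863 CPM. Of the let-7 family 3 fell and 1 rose of 7 (camera adjusted p = 0.395), and 3 of 5 members of the miR-99, miR-100 and miR-125 group fell (camera adjusted p = 0.197), with miR-100 at 1593 ± 607 against 41150 ± 9484 CPM. miR-10a rose to 6309 ± 1856 from 780 ± 585 CPM as 1 of 4 members of the HOX-cluster list (camera adjusted p = 0.747), and 1 of the 2 members of the miR-181 family, miR-181a, was called higher. No pluripotency miRNA was tested.

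**Figure D3:**
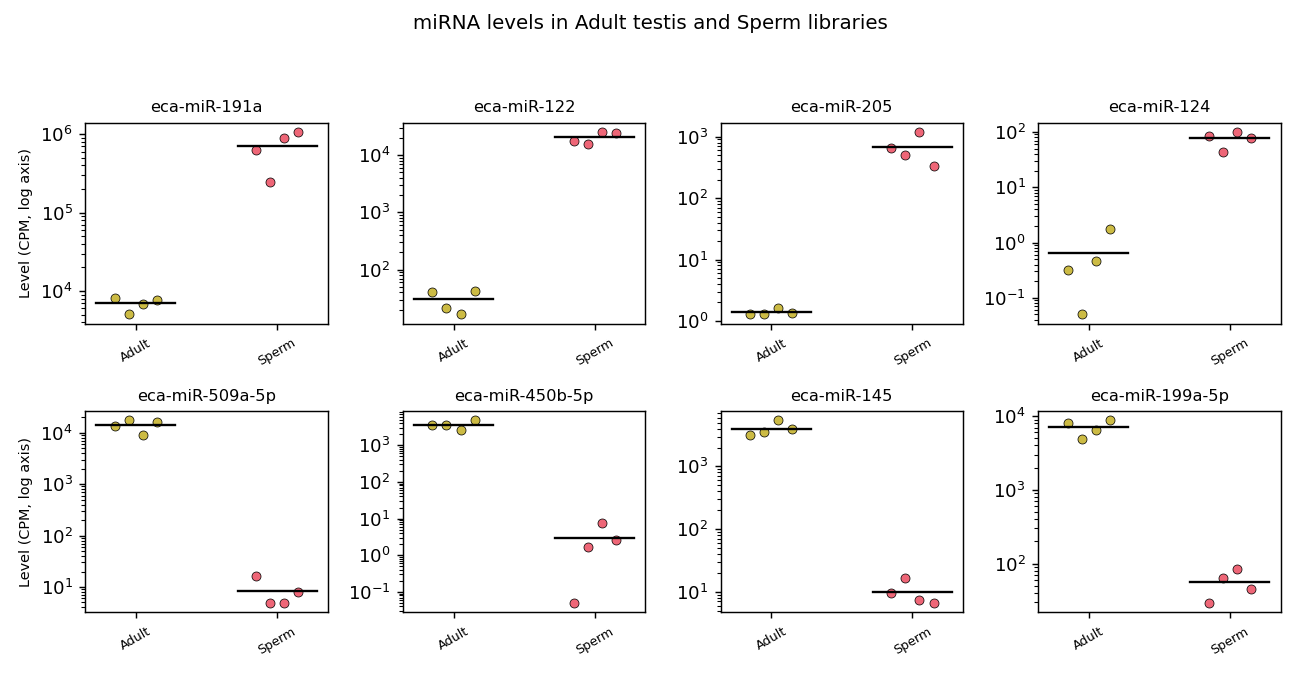
Levels of 8 miRNAs in 4 Adult testis and 4 Sperm libraries, in CPM on log axes; points are libraries and bars are group means. miR-191a, miR-122, miR-205 and miR-124 lie higher in every Sperm library, and miR-509a-5p, miR-450b-5p, miR-145 and miR-199a-5p lie higher in every Adult library; a library without counts (1 for miR-124, 1 for miR-450b-5p) is drawn at 0.05 CPM.

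edgeR called 132 of 162 miRNAs, 68 higher and 64 lower in Sperm, and camera called 0 of 14 lists (5 at an unadjusted p under 0.05). This 0 rested on Sperm 2, without which 4 lists were called, the X-linked miR-506 region, stromal, off-tissue and miR-30 lists (adjusted p = 0.186 each with an estimated correlation and all libraries), and on the scaling, as median-of-ratios factors gave 3 and no scaling beyond the total 1. fry, which does not compare a list with other miRNAs, called 12. For every list the counts were the same when adjusted over the list alone. The groups did not overlap for 121 miRNAs (74.7%), where chance gives 2.86%. The split followed the scaling: against a median log2 change of 0.06 with TMM, it was 61 higher and 77 lower with median-of-ratios factors (median -0.61), 36 and 86 without scaling beyond the total (median -1.61), 58 and 84 with all 17 libraries in the fit (median -0.82), 47 and 78 with all entries (median -1.01) and 50 and 81 without miR-191a, miR-30d and miR-34c (median -1.10). Without scaling beyond the total the calls of miR-34c, miR-34b-5p, miR-182, miR-30c, miR-9a, miR-451, miR-146a, miR-382 and miR-15b ended. Those of miR-181a and miR-20a took the other sign. Leaving out Adult 20 moved 16 of the 56 named folds by over 1.5 times and ended the calls of miR-451, miR-20a (0.78) and miR-181a (0.56). Of the moved folds 14 stayed called: miR-124 (6.09), miR-135a (4.47), miR-15b (2.01), miR-16 (3.37), miR-30b (3.22), miR-30e (3.19), miR-449a (2.55), miR-449b (3.15), miR-499-5p (5.26), miR-145 (-9.23), miR-195 (-6.92), miR-424 (-9.46), miR-450a (-8.10) and miR-503, which has 2 sperm counts and is given above as a ratio. Leaving out Sperm 2 moved 6, all still called: miR-34c (1.64 in place of 2.25), miR-34b-5p (1.82 in place of 2.59), miR-20b (-8.66), miR-199b-5p (-5.83), and miR-503 and miR-767-5p, then without sperm counts. Without Sperm 3, miR-450b-5p (-11.44) and miR-99b (-3.69) moved as far, as did miR-124 without Adult 4 (7.75) and, besides miR-451, miR-508-5p and miR-509b without Adult 33, both without sperm counts.

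Of the counts in the kept annotated and predicted entries, where a read may count more than once, predicted hairpins took 10.2 ± 1.04% in Infant (SD, n = 3), 13.2 ± 0.84% in Pre-puber (n = 3), 14.6 ± 1.95% in Puber (n = 3), 17.3 ± 3.05% in Adult (n = 4) and 19.1 ± 4.58% in Sperm (n = 4). Of them, 3 held the full mature sequence of a known miRNA that the annotated entries lacked, with positions as given in the table for EquCab3.0. The hairpin holding miR-202, a miRNA of the gonads, at chromosome 1, 594418 to 594474 on the plus strand, rose from 10170 ± 5890 CPM in Infant to 64260 ± 30230 in Adult (log2 fold change 2.66 ± 0.49 SE, edgeR adjusted p = 0.000231). It fell to 309 ± 194 CPM in Sperm from 46410 ± 17780 in Adult (-7.23 ± 0.56, adjusted p = 3.3e-16). The hairpin holding let-7i (chromosome 6, 80187888 to 80187965, plus strand) fell from 106300 ± 8096 CPM in Infant to 33330 ± 9573 in Adult. That holding miR-26b fell (chromosome 6, 7834343 to 7834399, plus strand) from 25920 ± 11700 to 3903 ± 1139. From Adult to Sperm, the let-7i hairpin fell by 1.37 on the log2 scale and the miR-26b hairpin rose by 2.86. Of 731 tested hairpins, 492 were higher and 12 lower in Pre-puber than in Infant, 417 and 2 in Puber than in Pre-puber, 0 and 0 in Adult against Puber (22 at an unadjusted p under 0.05, with no other tool run). The numbers were 671 and 15 in Adult than in Infant. Of 620 tested in the other fit, 272 were higher and 137 lower in Sperm than in Adult. These are numbers of entries, and 766 of the 1459 hairpin identifiers shared a stretch of 14 bases with another, so they are not independent.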

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

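In this part, the tests of a label swap, of the depth of the Adult libraries against the hairpins and of the sperm extraction were chosen after the result was seen, as were the tests of Adult admixture as the whole rise and of miRNAs above all Adult libraries, while the tests of Sperm against Adult without 3 miRNAs or with thinned libraries were chosen after seeing the data but before their own results.

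Of 108 groups of 4 libraries examined, 10 (9.26%) held 1 library far from the others by Dixon's test, where chance gives about 1 in 20. Sperm 2 was that library 6 times. It held 259700 CPM of miR-34c against 81000 to 91290 in the other sperm libraries, 180800 of miR-21 against 69190 to 85820, and 111200 of miR-340-5p against 26550 to 35330. It also held 536.2 of miR-190b against 248.9 to 276.5, and 1.635 CPM of both miR-503 and miR-767-5p against 0. These last 2 rest on 2 counts each, and where 3 libraries are at 0 any count passes, so they say nothing about Sperm 2. Apart from 3 groups with 3 or more libraries at 0, there were 8 such libraries in 105 groups (7.62%), 4 of them Sperm 2. Adult 20 was that library 3 times, with 127300 CPM of miR-10b against 51420 to 64200, 172.2 of miR-1298 against 15.89 to 27.97, and, as scaled with sperm, 100200 of miR-21 against 64230 to 68830. Adult 33 held 1.597 CPM of miR-205 against 1.275 to 1.328. Without Sperm 2, 132 miRNAs were called between Sperm and Adult, 128 of them among the 132 of all libraries.

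The column of totals, which no comparison used, held 12.53 M (mega) counts beyond the sum of the 17 libraries, in 1254 of 1763 entries. Where they come from was not tested.

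Pre-puber 14 lay with the Puber libraries by its correlation across miRNAs. Its log2 CPM across miRNAs (not independent replicates) correlated at 0.982 with the mean of the Puber libraries, against 0.939 with the mean of Pre-puber 3a and 3b. Library by library, the correlation was 0.9726, 0.9752 and 0.9762 with Puber 10, 11 and 19, and 0.9408 and 0.9315 with Pre-puber 3a and 3b. Single miRNAs did not all lie at Puber levels. Pre-puber 14 held 2621 CPM of miR-34c, 54.56 of miR-34b-5p and 618.7 of miR-449a, against Puber means of 15910, 458.7 and 2238. Those of miR-20b (3788 against 2881) and miR-514a (711.4 against 397) lay above the Puber mean. A label swapped with a Puber library needs a Puber library out of place, and 0 of 3 correlated better with 3a and 3b than with the other Puber libraries. Adult testis RNA mixed into the library as the whole rise would need 1 share for all miRNAs higher in Adult, but over the 20 of 48 such calls against Infant with at least 50 CPM in Adult, no overlap of the groups and over 2 times the level of Pre-puber 3a and 3b, implied shares ran from 4.403% (miR-34b-5p) to 289.7% (miR-514a), 5 were over 100%, 3 miRNAs (miR-514a, miR-20b and miR-509a-5p) lay above all 4 Adult libraries, and 18 of 20 needed more than the 5.259% that miR-34b-5p allows, whichever Adult library and Pre-puber 3a or 3b were used. Both miR-17 and miR-106a, of nearly the same counts, are among the 5 over 100% and may not be separate. A smaller Adult share beside another cause cannot be told apart, as the ratio of the 75th to the 25th percentile of the shares, 4.103, lay above the highest of the Adult libraries, 2.125, but below 2 times it, the bound set before the test. A single wrong label and an animal further into puberty than its stage label remain open and were not tested.

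A total of 671 predicted hairpins were higher in Adult than in Infant testis, and 15 lower, out of 731. The same reads counted for several hairpins do not account for the direction, since with 1 hairpin for each group of shared sequence, 178 of the 190 groups with a call (93.68%) were higher in Adult. Greater depth does not either, since Adult libraries held 0.3423 of the annotated counts of Infant libraries. Hairpins that shared a stretch of 14 bases with others rose more often, 96.2% of 571 against 76.3% of 160 (odds ratio 7.741, 95% interval 4.29 to 14.28, Fisher's exact p = 4e-13 over hairpins that are not independent). The largest group alone held 369 of these 571, 365 of them higher, so the interval and p are too narrow and too small. With 1 hairpin for each group, 178 of all 226 tested groups were higher, against 122 of the 160 among them that shared no sequence. Whether repeated sequence marks the hairpins that rise thus cannot be told from the test over hairpins. The difference in age between the groups remains open and was not tested.

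Most miRNAs differed between Sperm and Adult testis, 132 of 162. A few abundant miRNAs are not the whole source, since 111 of the calls remained in the same direction without miR-191a, miR-30d and miR-34c, and lower depth is not, since 127 remained with all 8 libraries thinned to the smallest total. The extraction cannot be told apart from the cell type, as 0 Adult testis libraries were made with the sperm protocol. The difference between sperm and whole testis itself remains open and was not tested.

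Other groupings of the libraries were counted for each comparison. Taking libraries that share a title number as separate samples, no other split gave as many calls for the testis stages (88 calls, 29 at most in the other splits among 100). On the same terms none did for Adult against Infant (95 calls, 27 at most in the other splits of 35). If Infant 31a and 31b are 1 animal, 2 Infant and 4 Adult samples make 15 splits, too few for a share under 0.05. For Sperm against Adult, where no title number is shared within a group, none did either (132 calls, 0 at most in the other splits of 35). The 1 split as large is the real one each time. These shares are thus the smallest possible, are not adjusted over the comparisons and do not by themselves exclude chance. Pre-puber against Infant (44 calls, 0 at most in the others) and Puber against Pre-puber (2 calls, 0 at most in the others) have 10 splits, too few for a share under 0.05. For Adult against Puber the real count is 0, so all 35 splits are as large by construction and their number decides nothing. The highest other split, Puber 19 with Adult 13, 33 and 4 against the rest, gave 12 calls in the same fit. It is the highest of many splits, and what it reflects was not tested.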

How the results depend on the processing

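In this part, the fit of all entries, the list tests without Pre-puber 14 or Sperm 2, and the tests of Sperm against Adult without its 3 most abundant miRNAs or with thinned libraries were chosen after seeing the data. Over 142 named values, 2737 of 2909 alternatives (94.1%) kept the direction and the side of the threshold, 166 kept the direction but lost the call and 6 took the other sign. All alternatives kept the call for 9 of 10 named miRNAs of the stages, 13 of 29 in Pre-puber against Infant, 0 of 1 in Puber against Pre-puber, 33 of 46 in Adult against Infant and 45 of 56 in Sperm against Adult. Of 247 alternatives to the 21 counts and differences, 202 (81.8%) were rated the same, 13 weaker, 30 stronger and 2 of the other sign. For a difference, the same meant the same sign and side of the threshold. For a number of calls it meant a total within 1.5 times, whichever members were called and in whichever direction. Adult against Infant without scaling beyond the total was thus rated the same, with 84 higher and 21 lower against 48 and 47. The cause was not tested for any of the changes below, except that fewer libraries or miRNAs enter some fits by construction.

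With all entries in the fit, the calls were 169 of the annotated miRNAs over the stages, 105 in Puber against Pre-puber and 149 in Adult against Infant. The log2 fold changes of miR-499-5p (Puber against Pre-puber, -0.126), miR-122 (Adult against Infant, -0.2016) and miR-409-5p (Adult against Infant, -0.3798) took the other sign, each without a call. In Sperm against Adult, miR-181a (-0.5148) and miR-20a (-0.1612) did so without scaling beyond the total, and miR-181a (-0.06693) without the 3 abundant miRNAs. Pre-puber against Infant gave 26 calls from its own libraries alone and 29 with summed title numbers. Puber against Pre-puber gave 8 calls with median-of-ratios factors, 9 without scaling beyond the total, 7 by upper quartiles, 16 with DESeq2, 19 with limma-voom, 7 with all 17 libraries, and 0 with the stricter filter, from its own libraries alone and with summed title numbers. Adult against Puber gave 1 without scaling beyond the total, 10 with DESeq2 and 19 from its own libraries alone.

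No list was called with an estimated correlation (0 in place of 3, 1 and 4 for Pre-puber against Infant, Puber against Pre-puber and Adult against Infant). In Adult against Puber, fry called 1 list (stromal), and median-of-ratios factors and no scaling beyond the total each 1 (the miR-183, miR-96 and miR-182 cluster). fry called 8 lists in Adult against Infant and 12 in Sperm against Adult, where median-of-ratios factors called 3 and no scaling beyond the total 1. Without Pre-puber 14, the lists called were 2 in Pre-puber against Infant (the DLK1-DIO3 region ended), 3 in Puber against Pre-puber, 1 in Adult against Puber and 4 in Adult against Infant, and without Sperm 2 they were 4 in Sperm against Adult.

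Leaving out each library in turn gave 72 to 95 calls for the stages, 33 to 42 for Pre-puber against Infant, 0 to 30 for Puber against Pre-puber (30 without Pre-puber 14), 0 to 7 for Adult against Puber (7 without Puber 19 and without Adult 20), 75 to 92 for Adult against Infant and 130 to 137 for Sperm against Adult. For detected miRNAs it gave differences of 6.667 to 12.17, 4.5 to 10.0, -6.333 to -1.0, 10.33 to 15.67 and -42.0 to -35.08 in the order of the comparisons. For the share of the 10 most abundant they were -5.815 to -2.557, -5.61 to -0.87, -4.6 to 0.14 (without Puber 10), -11.3 to -8.123 and 7.223 to 10.47 percentage points (10.47 without Adult 20, with an exact permutation p of 0.0286). Thinned to the smallest total, Adult libraries held 0.6667 more detected miRNAs than Puber libraries, the other sign, and 24.67 more than Infant libraries (exact permutation p = 0.0286). The share of the single most abundant miRNA differed by -12.79 points in Adult against Infant and 25.43 in Sperm against Adult, and that of the 20 most abundant by 6.442 in Sperm against Adult (exact permutation p = 0.0286 each, the smallest these libraries allow).

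No paired analysis was possible because the groups share fewer than 2 replicate numbers. Depth sets the lowest level that can be told from 0, 0.7213 CPM in Sperm (3 counts over the group). In simulated data, 15 to 35% of 2-fold changes were recovered, so changes of that size can be missed in every comparison, and depth was not varied there. Nor did a simulated library lie apart from its group. In the real data, miR-34c was not called at means of 909.6 CPM in Pre-puber and 15910 in Puber.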

Other observations

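In this part, both tests of X-linked miRNAs were chosen after the result was seen, and the interval of the second was added after its median.

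X-linked miRNAs stood apart in sperm, and those named here were chosen after their values were seen. Of 32 tested miRNAs whose precursors lie on the X chromosome, 26 fell from Adult testis to Sperm and 4 rose, with a median log2 fold change of -4.28 (-3.94 with the 4 that had no sperm count at their bound). Of 129 autosomal miRNAs, 37 fell and 64 rose, with a median of 0.87. Beside the miR-506 family, the fallen ones included miR-450a, miR-450b-5p, miR-450c, miR-424, miR-503 and miR-542-5p, which lie within 1 cluster, and miR-374a, miR-374b, miR-504, miR-98, miR-362-5p, miR-532-5p and miR-660. Those that rose were miR-8908k, from 38.7 ± 14.6 to 1550 ± 238 CPM (SD, n = 4 each), miR-8908j, miR-8908g and miR-18b. Among the 19 tested predicted hairpins on the X chromosome, 5 fell and 11 rose, against 132 and 261 of 601 elsewhere. The 2 of these hairpins with the highest sperm means rose to 30610 ± 4910 from 474 ± 69.2 CPM and to 6301 ± 4012 from 357 ± 87.4 CPM (SD, n = 4 each). Without scaling beyond the total the median of all tested miRNAs moved from 0.06 to -1.61, a shift larger than the rises of miR-8908g (1.11) and miR-18b (1.28) and than the autosomal median, so these directions depend on the scaling. A shift common to all miRNAs leaves the difference between X-linked and autosomal miRNAs unchanged by construction.

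A hypothesis is that the fall is shared over the X chromosome and not carried by 1 cluster. Taking 1 median for each cluster of precursors within 10 kb, 14 of 15 X-linked clusters lay lower in Sperm, against 41 of 103 autosomal clusters, and the difference of the cluster medians was -5.333 (two-sided permutation p = 8e-05 from 100000 draws, adjusted p = 4e-04 over 5 comparisons), also with the miRNAs without sperm counts at their bound. The difference was 0.34, 0.18, -0.26 and 0.73 in the 4 testis comparisons, with adjusted p from 0.296 to 0.471. Of the 14 lower X-linked clusters, that of miR-20b (-7.99), miR-106a and miR-18b (1.28) counts as lower only by its median. This is miR-106a at -0.04, which was not called. Its counts in Infant and Pre-puber were nearly those of miR-17, so its value may not be that of a separate miRNA. In the miR-506 family region, miR-514a, miR-508-5p and miR-509a-5p were placed in separate clusters, which may not be independent. The result is consistent with a fall that extends over the X-linked miRNAs of the annotation, while the predicted X-linked hairpins did not share it.

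A lower share of testis somatic RNA in sperm could also lower X-linked miRNAs. The 14 X-linked miRNAs that were higher in Adult than in Infant, which are thus not among those lost as germ cells accumulate, had a median log2 fold change of -4.522 in Sperm, against 0.06 for all tested miRNAs. Of them, 8 fell, 4 rose and 2 were not called, and the exact 95% interval of the median ran from -9.60 to 1.28. This interval takes the 14 as independent, which neighbours may not be. Of those that did not fall, miR-8908k, miR-8908j, miR-8908g and miR-8908f share a cluster, and miR-18b and miR-106a share another. The interval held 0 and its upper end rests on these clusters, so the somatic share and a fall within germ cells cannot be told apart here.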
